A study of Mus musculus with 249 samples.

How the data were processed

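Brain RNA of 249 mice from an F2 intercross was measured on 1 array with 2 colours for each animal. Per the labels the parental strains were C57BL/6J and C3H/HeJ on a background lacking ApoE, the animals ate a Western diet from 8 to 24 weeks of age, and both sexes were included, but sex, genotype and array batch are not given for each animal. The labels name 330 mice in the cross and the 249 arrays are the ones analysed here. Animal RNA carried Cy3, and a reference pool that combined the same amount of RNA of every sample carried Cy5.

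The deposited values are log10 ratios of animal to pool, 1 per probe and array. The labels give the colours of the channels, while the scanner, the background treatment and the dye normalization are not given in the sources used here. The base and the direction were read from the values. The upper component of the Y-linked transcripts lay at 0.284 and 0.302, near the log10 of 2 (0.301) that a pool of both sexes in about equal parts gives, which also makes positive values higher in the animal than in the pool. The scale ended at exactly -2 and 2, with 83 values at the upper limit and 113 at the lower. Array medians ran from -0.00627 to 0.0250, so the arrays had been centred before deposit, by a method that stays unknown. Across the 30876 pairs of arrays the correlation over probes had a median of 0.306 and a lowest value of -0.352, and 6 pairs lay under -0.3. The direction was kept for all arrays because the labels give 1 dye order for them and animals set against a pool of the same animals can lie on opposite sides of it. There are no replicate arrays of 1 animal, and the number of arrays limits the precision. Intensities are not analysed here, so signal over background is unknown.

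The array held 23388 probes, of which 13645 carried 1 gene symbol, 48 carried several and 9695 carried none. A gene's value was the mean of all probes that named that gene alone and were measured on at least 90% of the arrays, with gaps filled by the probe's mean over animals. Of all values 0.710% were missing, 22282 probes were measured on every array, and 335 probes, 201 of them with a symbol, fell below the required share. The 13444 probes used gave 11508 genes. Assembly GRCm38.p6 was used for current symbols and for gene order only, and it placed 10674 genes, 10278 of them on autosomes. Symbols in older form were matched through its synonyms, and 834 genes were not placed. For 1 sample the title and the source name gave different animal numbers, and the source name was used.

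With 1 group of animals and no labels that divide them, the variation between animals was the measurement. The spread of each gene was its SD over animals, with a standard error from 1000 bootstrap resamples, and the mean against the pool was its mean. Agreement of probes was the Pearson r between probes of 1 gene, set against 1000 random pairings of probes of different genes. List coherence was the mean pairwise Pearson r of a list's members, tested one-sided against 10000 random gene lists of the same size matched on SD in 20 bins, with Benjamini-Hochberg adjustment over the lists tested. List scores, the mean z of the members, were compared by Pearson r and Spearman rho with 100000 permutations of animals, two-sided, with adjustment over the pairs. A score or gene was called clustered when a normal mixture with 2 components and 1 variance beat 1 normal by more than 10 in BIC and the means lay at least 3 within-component SD apart, and clustered scores entered no correlation. Shares of animals have exact Clopper-Pearson 95% intervals. The Y-linked transcripts were described in this way and no animal was assigned a sex.

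For each autosomal gene the likelihood of 3 normal components with weights of 25%, 50% and 25% and 1 variance was set against that of 1 normal, with p from 100000 simulated normal sets. Genes were called discrete at an adjusted p under 0.05, outer means at least 2 within-component SD apart and an excess kurtosis under 0. Neighbour correlation was the mean r squared of autosomal genes by the number of places between them on a chromosome, tested one-sided against 1000 random gene orders. The smallest p these tests can give is 0.0001 for the random lists, 1e-05 for the permutations of animals and the simulated sets, and 0.001 for the random orders.

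The 41 gene lists, of cell types, brain regions, tissues that a dissection can bring along, and pathways, were fixed before the data were examined, as were the tests, the other settings tried and the rule for named genes. The lists held 473 genes, 343 of them measured, and a list needed 4 measured members to be tested. The rule named the 25 genes with the largest SD, the 3 members of each list closest to the other members and the member farthest from them, the 20 discrete genes with the largest gain in likelihood, every measured Y-linked gene and known strain variant, Apoe, and the 10 pairs of adjacent genes with the largest absolute r whose symbols differ in their first 3 letters. Lists of lung, liver, testis, kidney, intestine, and neutrophils and bone marrow were added after the values were seen.

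On simulated data with 249 animals, coherence was called in 20 of 20 lists with a mean r of 0.1 and in 2 of 40 unrelated lists. Unrelated simulated genes were drawn independently of each other, while gene pairs in random orders of the data had a mean r squared of 0.0619. The share called at 0.1 therefore need not hold for the data. Simulated additive loci were called in 39 of 50 genes at outer means 6 SD apart, in 1 of 50 at 4 SD and in 0 of 50 at both 3 SD and 2 SD, against 1 of 11108 normal genes. Of genes with heavy tails 0 of 200 were called, which is no measure of false calls, since the condition on kurtosis is set against such genes. These calls were adjusted over 11508 simulated genes, against 10278 autosomal genes in the data. Neighbour correlation was called at 6 of 6 distances in 1 simulated set in which 20% of genes had a local locus. It was called at 0 of 6 distances in 1 set without such loci.

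The other settings were centring or quantile normalization of the arrays, the probe with the largest SD of each gene, only probes measured on every array, leaving out the 12 arrays of largest spread, the median absolute deviation, Spearman correlation, random lists not matched on SD, residuals on the Y-linked genes, removal of principal component 1, neighbours without similar symbols or without discrete genes, and other limits for the discrete genes. Leaving out the array of animal 144, alone or for list coherence with that of animal 208, and fitting animals with lower and higher numbers apart, were added after the values were seen. So was a test of list correlations with the means of 10 blocks of consecutive animal numbers removed and 100000 permutations of animals within blocks. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.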

Results

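Gene expression was measured in the brains of 249 F2 mice from C57BL/6J and C3H/HeJ parents that lacked ApoE, each on 1 array against a pool of the same animals. The animals form 1 group, and the question the labels give is how inheritance shapes expression in the brain. Values are log10 ratios of animal to pool, so that a difference of 0.301 is a factor of 2. There was 1 array per animal and no replicate. The SD of an array over its probes had a median of 0.0764, and animal 144 had the highest, 0.392.

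The array of animal 144 carried transcripts of lung and was low in those of nerve cells. Surfactant protein C (Sftpc), made by alveolar cells, stood at 1.24 on it, against -1.45 ± 0.104 (SD, n = 248) on the other arrays. The phosphate transporter Slc34a2 and surfactant protein D (Sftpd) stood at 1.44 and 1.13. The synaptic gene Snap25 stood at -1.99, Nefm, a neurofilament subunit, at -1.82 and the tubulin Tubb3 at -1.48. The median of the list of neurons was -1.28 on this array and between -0.113 and 0.0684 on the other 248, and the median of the lung list was 0.776 against -1.10 to -0.613. The lung genes were chosen after their values were seen. Because the array's place in the set is doubtful, the main counts are also given without it.

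**Figure D1:**
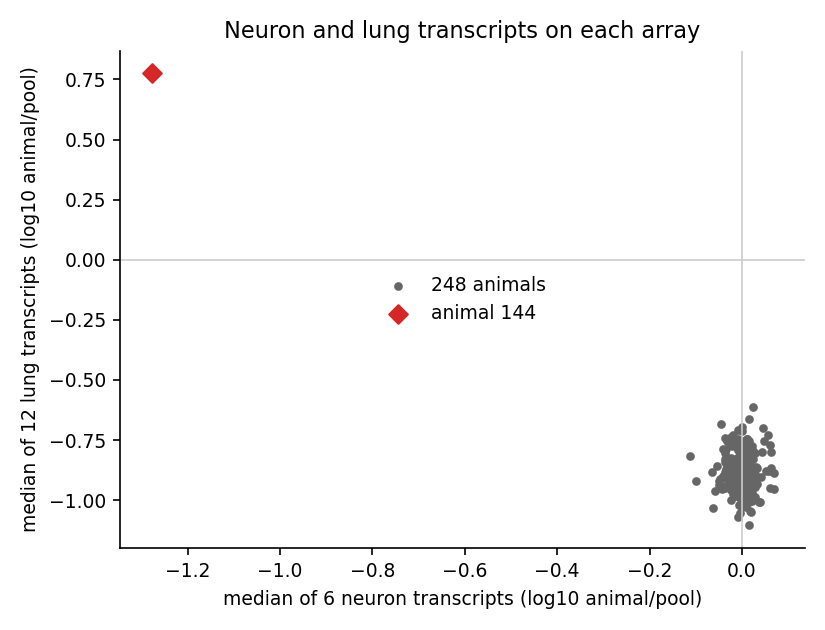
Median log10 ratio of the lung list against that of the neuron list, 1 point per animal. Animal 144 lies at 0.776 for lung and -1.28 for neurons, apart from the other 248 animals.

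Most lung transcripts lay far below the pool in the other animals. Of the 12 measured genes of the lung list 10 had a mean under -0.3, and the highest mean was -0.0193. The lowest means of all genes were those of Sftpc, surfactant protein B (Sftpb, -1.44) and the club cell secretoglobins Scgb3a2 (-1.37) and Scgb1a1 (-1.32), followed by the esterase Ces1d (-1.17), Prl (-1.14) and Slc34a2 (-1.01), and the alveolar gene Ager lay at -0.803. In the values as deposited, Sftpc was 27.9-fold higher in the pool than the mean of the 248 animals, and Sftpd 10.2-fold. Signal over background is unknown, so the differences in transcript may not equal these folds. Of 11508 genes, 51 had a mean under -0.3 (53 without animal 144) and 0 a mean over 0.3, while 96.7% lay within 0.05 of the pool. The pool averages animals before the log is taken, so the mean of a gene that varies widely tends to lie under 0. Prl is such a gene (SD 0.758 without animal 144, against 0.104 for Sftpc). How much of the balance between 51 and 0 this makes up was not measured. As the labels give no dye swap, dye bias in the mean of a single gene was not measured.

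Y-linked transcripts had the largest SD of all genes, 0.951 for Eif2s3y and 0.787 for Kdm5d. Eif2s3y, a translation initiation factor gene on the Y chromosome, fell into components with means of -1.59 and 0.284, a 75.5-fold difference, and 121 of 249 animals were in the upper one (48.6%, exact 95% interval 42.2% to 55.0%). Kdm5d, a histone demethylase gene, had means of -1.25 and 0.302 and 122 animals in the upper component. Both genes placed 248 of the 249 animals on the same side and 1 animal on different sides. The other 3 members of this list, Xist among them, were not measured under a listed name, so the list was not tested for coherence.

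After the Y-linked pair, the genes of largest SD between brains were hormones of the pituitary gland. Prolactin (Prl) had an SD of 0.757 ± 0.0293 (bootstrap SE, n = 249), the glycoprotein hormone alpha subunit (Cga) 0.743, growth hormone (Gh) 0.695 and the thyrotropin beta subunit (Tshb) 0.532, against a median of 0.0586 over all genes. From the 5th to the 95th percentile of animals these spanned 166-fold for Prl, 181-fold for Cga, 98.2-fold for Gh and 43.4-fold for Tshb. Next came Gbp2b, a guanylate-binding protein (0.522), Pttg1, securin (0.505), the adaptor Skap2 (0.502), the zinc finger gene Prdm16 (0.475) and Ccnb1ip1 (0.471). Gabra6, the GABA receptor subunit of cerebellar granule cells, had an SD of 0.396, S100a5 0.380, the myelin lipid enzyme Ugt8a 0.350, the chemokine receptor Ccr6 0.337, the pituitary transcription factor Pitx1 0.325 and Lrrc6 0.320. Ngp (0.356), a granule protein of neutrophils, and S100a9 (0.331), abundant in the same cells, were also among the 25. Meioc (0.438), SPATA22 (0.421), Zdhhc11 (0.411), Prl6a1 (0.348) and Clca2 (0.333) reached both ends of the scale in single animals, and CAPN13 (0.351) its lower end. Apoe, which these animals lack as a functional gene, had an SD of 0.0399, at percentile 20.7.

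An SD of 0.2, a factor of 1.58, was reached by 119 genes, or 104 without animal 144, and the 25 genes of largest SD were the same 25 without it. The count was 35 by the median absolute deviation, which a few outlying animals do not move. Probes of the same gene correlated with a median r of 0.267 over 4820 pairs in 1283 genes, against 0.00959 for probes of different genes (random pairings, one-sided p = 0.001, the smallest they can give). The median was 0.801 over the 301 pairs in which both probes had an SD of at least 0.1.

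The pituitary genes divided the animals into a larger part with low and a smaller part with high levels. Prl was high in 67 animals (26.9%, exact 95% interval 21.5% to 32.9%) by 34.4-fold, Gh in 58 (23.3%) by 32.6-fold, Cga in 62 (24.9%) by 37.8-fold and Tshb in 57 (22.9%) by 13.0-fold. Pitx1 was high in 52 animals by 5.40-fold, and for Prl and Gh other animals lay between the 2 levels. The cerebellum showed the opposite shape, a few animals with low levels: Gabra6 was low in 15 animals (6.02%) by 31.3-fold, Cbln1, the synaptic organizer of granule cells, in 18 by 4.32-fold and Pcp2, a Purkinje cell gene, in 18 by 2.52-fold. Without animal 144 Gabra6 was low in 14 animals by 28.9-fold, Cbln1 in 17 by 3.94-fold and Pcp2 in 18 by 2.44-fold. In the olfactory bulb list Doc2g was high in 62 animals by 2.05-fold. The single genes shown here beyond the 25 and the list members were chosen after their values were seen.

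**Figure D2:**
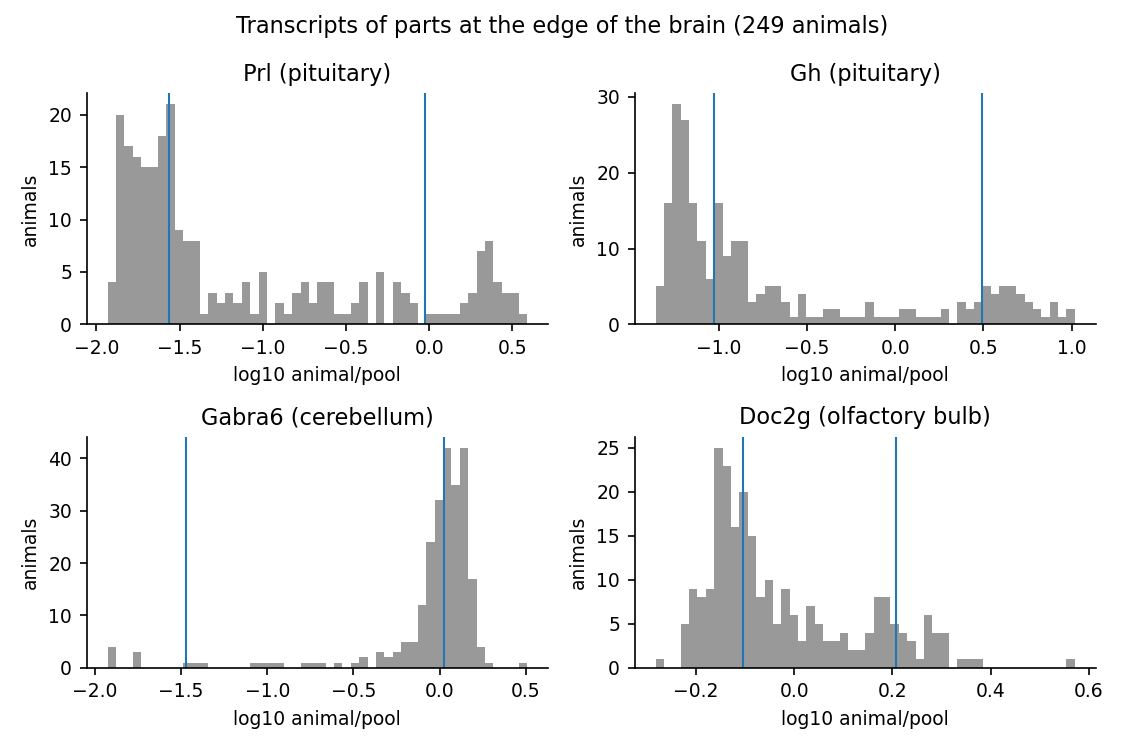
Histograms of the log10 ratio of Prl, Gh, Gabra6 and Doc2g over the 249 animals, with the means of the 2 fitted components as lines. Prl is high in 67 animals and Gh in 58, while Gabra6 is low in 15 (14 without animal 144).

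Many groups of genes that mark a cell type, region or response varied together between brains. Of 40 lists tested, 30 were coherent against random lists at an adjusted p under 0.05. Without animal 144 the number was 25, of which 22 were shared, so 8 lists rested on that animal. The random lists were matched on SD and not on position, and neighbouring genes varied together as well (below). What members that lie close together on a chromosome add to a list's mean r was not tested. Closest and farthest members are those over all 249 animals unless stated otherwise. The pituitary list had a mean r of 0.717 over 8 members (random lists, adjusted p = 0.000333), with Gh, Cga and Pitx1 closest to the rest and Gal, a neuropeptide, farthest. The cerebellum list (0.607, 10 members) was led by Cbln1, Pcp2 and Gabra6, with Eomes farthest. These averages include the step between low and high animals described above. The olfactory bulb list (0.278, 8 members) was led by Eomes, Doc2g and Tbx21, which spanned 4.97-fold, 2.98-fold and 6.34-fold from the 5th to the 95th percentile, with Calb2 farthest. Tbx21 was itself called discrete (below), so its span need not belong to the region.

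Genes of blood and of tissue around the brain formed further groups. Red cell genes had a mean r of 0.613 over 5 members: the haemoglobin genes Hbb-b2 and Hbb-b1 spanned 5.52-fold and 4.44-fold, and Alas2, the haem synthesis enzyme of red cells, 2.60-fold, with Epb42 farthest. Skeletal muscle genes (0.421, 8 members) were led by the troponins Tnni2, Tnnt3 and Tnnc2, and Tnnc2 spanned 3.70-fold, while Pvalb did not follow them. Meninges and fibroblasts (0.180, 10 members) were led by Fmod, Islr and Col1a2, with Lum farthest (Igf2 in place of Col1a2 without animal 144). Microglia (0.238, 10 members) were led by Trem2, the complement gene C1qc, which spanned 2.45-fold, and Csf1r, with Cx3cr1 farthest. Csf1r was itself called discrete, so its variation need not belong to the group. The lists of hypothalamic neuropeptides (0.189; Cartpt, Oxt and Hcrt closest, Hdc farthest) and oligodendrocyte precursors (0.144; Olig2, Cspg4 and Pdgfra closest, Gpr17 farthest) were coherent as well. Without animal 144 the farthest members were Slc4a1 for red cells, Crh for hypothalamic neuropeptides and Matn4 for oligodendrocyte precursors.

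Lists named for responses of cells gave another set. The interferon response had a mean r of 0.534 over 14 members, led by Ifit1, Ifit3 and Usp18, with Isg15 farthest, and MHC class I 0.468 over 9 (0.308 without animal 144), led by B2m, Psmb9 and Psmb8, with Tapbp farthest. Immediate early genes, which neurons switch on with activity, had 0.401 over 11: Egr2 spanned 4.26-fold, Dusp1 2.38-fold and Fos 1.67-fold, with Npas4 farthest. The glucocorticoid response had 0.187 over 12, and its leading genes Plin4, Sgk1 and Sult1a1 spanned 4.80-fold, 3.07-fold and 2.18-fold, with Hif3a farthest. Plin4 was itself called discrete (64, 128 and 57 animals, 3.29-fold, chromosome 17, simulated normal sets, adjusted p = 0.00455), so its span need not belong to a response. Oxidative phosphorylation had the highest mean r, 0.743, over only 4 measured members, Ndufa2, Atp5j, Ndufa1 and Ndufs4. The cytosolic ribosome had 0.247 (Rpl13, Rplp0 and Rpl27 closest, Rps3 farthest), the unfolded protein response 0.101 (Pdia4, Sdf2l1 and Calr closest, Dnajb9 farthest), and cholesterol efflux and LXR targets 0.155 (Abcg1, Pltp and Scd1 closest, Apod farthest). Striatum genes had 0.457 over 11 members with Ppp1r1b, Drd2 and Penk closest and Pdyn farthest, and 0.253 without animal 144. Without that animal MHC class II (H2-Aa, Ciita and H2-DMb1 closest, H2-Ea farthest) went from 0.443 to 0.143, and immunoglobulin and lymphocytes (Cd79b, Cd3d and Ms4a1 closest, Cd3e farthest) from 0.442 to 0.217. Oligodendrocytes and myelin (Cldn11, Mal and Cnp closest, Ugt8a farthest) went from 0.238 to 0.158, and acute phase and inflammation (Tnf, Ccl2 and Saa3 closest, Saa2 farthest) from 0.198 to 0.0764. The 22 lists named in this and the 2 preceding paragraphs passed with and without it.

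Some of these ranks and calls rested on single animals. Without animal 144 the closest 3 members held Ighm in place of Ms4a1 for lymphocytes, Rasd2 in place of Penk for striatum, Arc in place of Fos for immediate early genes and H2-K1 in place of Psmb8 for MHC class I. They held H2-Eb1 in place of H2-DMb1 for MHC class II, Cxcl10 in place of Saa3 for acute phase and Srebf1 in place of Scd1 for LXR targets. The farthest were then Cd3g for lymphocytes, Arpp21 for striatum, Lcn2 for the glucocorticoid response, Aspa for oligodendrocytes, Il1r1 for acute phase and Lpl for LXR targets. With animal 208 left out as well, 20 of the 22 lists still passed, the interferon response at a mean r of 0.317 and MHC class I at 0.160. Acute phase and inflammation (0.0140, random lists, adjusted p = 0.306) and MHC class II (0.116, adjusted p = 0.0576) did not pass. Acute phase genes also did not pass without the 12 arrays of largest spread or by Spearman correlation, so their call rests on a few animals.

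The 8 lists that rested on animal 144, and whose closest members are ranked with it, were neurons, whose mean r went from 0.367 to -0.101 without it, glutamatergic cortical neurons (0.286 to 0.0663; Rtn4r, Tbr1 and Neurod6 closest), GABAergic interneurons (0.263 to -0.0376; Npy, Slc32a1 and Dlx1 closest), astrocytes (0.174 to 0.0753; Aldoc, Aqp4 and Gjb6 closest), ependymal cilia (0.194 to 0.0513; Ak7, Ccdc153 and Foxj1 closest), thalamus and habenula (0.0957 to 0.0356; Slc17a6, Ntng1 and Rgs16 closest), fatty acid oxidation and ketone use (0.230 to 0.0971; Angptl4, Acadl and Cpt2 closest), and cell division (0.149 to 0.0415; Birc5, Prc1 and Cdk1 closest). The lists of brain endothelium and pericytes (0.0634 to 0.139; Slco1c1, Esam and Kdr closest, Abcb1a farthest), monoamine neurons (0.0837 to 0.136; Ddc, Slc6a4 and Slc6a3 closest) and heat shock (0.0843 to 0.113; Hspa1a, Hsph1 and Hspb1 closest) passed only without it, and their members are ranked without it. Astrocytes passed again without animals 144 and 208 (0.0760, random lists, adjusted p = 0.0498). The other 7 did not pass either way: choroid plexus (mean r 0.0575; Folr1, Sostdc1 and Ttr closest), hippocampus (0.0535; Wfs1 closest), retina and pineal (0.0622; Sag closest), circadian clock output (0.0545; Tef, Bhlhe41 and Per2 closest), cholesterol synthesis (0.0634; Cyp51, Fdft1 and Sqle closest, adjusted p = 0.0714 against random lists), hypoxia response (-0.0176; Slc2a1 farthest) and known strain variants (-0.0256).

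**Figure D3:**
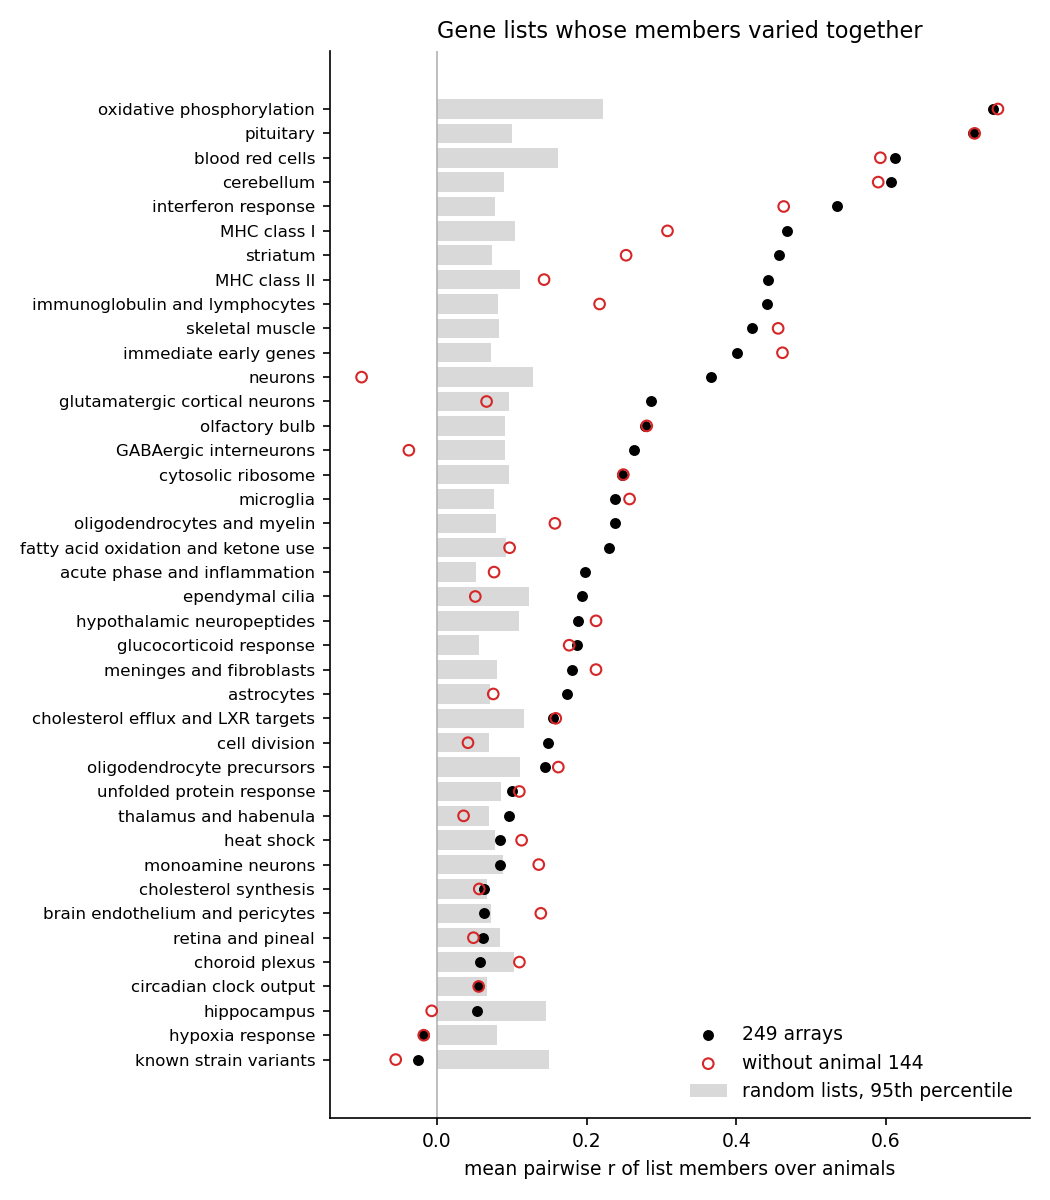
Mean pairwise Pearson r of the members of each list over all 249 animals and without animal 144, with the 95th percentile of the random lists. The list of neurons moves from 0.367 to -0.101, while that of the pituitary stays at 0.717 and 0.719.

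Scores of some groups were correlated across animals. A gene named in both lists of a pair was left out of both scores. A gene that several cell types express but a single list names stayed in. What such genes add to a correlation was not tested, nor was it for Cspg4 and Pdgfra of the precursor list. Oligodendrocyte precursor genes correlated with genes of meninges and fibroblasts (r = 0.382, rho = 0.384, permutation p = 1e-05 for each, the smallest these can give, adjusted p = 0.00015, r = 0.357 without the 2 animals farthest from the median). Meninges and fibroblasts also correlated with the olfactory bulb (r = 0.270, rho = 0.319, permutation p = 2e-05 and 1e-05, adjusted p = 0.00015, 0.260 without 2 animals) and with microglia (r = 0.221, rho = 0.260, permutation p = 0.00047 and 4e-05, adjusted p = 0.00235, 0.226 without 2 animals). Immediate early genes correlated with the glucocorticoid response (r = 0.198, rho = 0.20, permutation p = 0.00162 and 0.00157, adjusted p = 0.00607, 0.20 without 2 animals). The relation of oligodendrocyte precursors to the glucocorticoid response (r = 0.191, permutation p = 0.00262, adjusted p = 0.00786) had a rho of 0.117 (permutation p = 0.0662), was 0.115 without 2 animals and so rests on those animals.

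These 5, all of them positive, passed out of 15 pairs, because 24 of the 30 coherent scores formed clusters and entered no correlation. In 14 of the 24, 1 animal alone made up a cluster. That animal was not animal 144 for the cytosolic ribosome and the unfolded protein response, which still set 1 animal apart without animal 144. With animal 144 left out, 28 of 78 pairs passed, 25 positive and 3 negative, the strongest being oligodendrocyte precursors with brain endothelium and pericytes (r = 0.589, rho = 0.584, permutation p = 1e-05 for each, adjusted p = 7.09e-05, 0.550 without 2 animals). As the labels give no batch, the animals were split by their numbers into parts of 124 each. In the parts with lower and higher numbers r was 0.264 and 0.412 for precursors with meninges, 0.337 and 0.252 for meninges with olfactory bulb, 0.210 and 0.181 for microglia with meninges, and 0.596 and 0.545 for precursors with endothelium. It was 0.314 and 0.0852 for immediate early genes with the glucocorticoid response, a difference that was not tested.

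Arrays of animals close in number were more alike. With each gene's mean over the animals removed and animal 144 left out, arrays next to each other in number had a mean r of 0.0637, against -0.000477 over all pairs of arrays and at most 0.0353 in 1000 shuffled orders (p = 0.001, the smallest these can give). Without animal 144, 7 of the 13 list scores set against the number followed it, among them endothelium and pericytes (r = -0.254, rho = -0.282, permutation p = 7e-05 and 3e-05, adjusted p = 0.000195 for rho, r = -0.278 without 2 animals). The list correlations were therefore repeated with the means of 10 blocks of consecutive numbers removed and animals permuted within blocks, a test added after the values were seen. The same 5 pairs passed, with r of 0.368 for precursors with meninges, 0.319 for meninges with olfactory bulb, 0.219 for microglia with meninges, 0.242 for immediate early genes with the glucocorticoid response and 0.215 for precursors with the glucocorticoid response (permutation p of at most 0.00205, adjusted p of at most 0.00615). The last again did not pass by rho (0.144, permutation p = 0.0269, adjusted p = 0.0808). Leaving out animal 144 ended its call, with r = 0.0915 (rho = 0.0930, permutation p = 0.153 and 0.146, adjusted p = 0.289, 0.115 without 2 animals) and 0.119 within blocks (adjusted p = 0.149), and it was 0.00321 and 0.214 in the parts with lower and higher numbers. Without animal 144, 25 of 78 pairs passed within blocks, 23 of them among the 28 above, with r = 0.575 for precursors with endothelium (rho = 0.563, permutation p = 1e-05 for each, adjusted p = 7.8e-05). Differences finer than these blocks are not removed.

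Some autosomal genes fell into 3 levels, as a locus inherited in an F2 gives. Pttg1, which keeps sister chromatids from separating before anaphase, had means of -1.06, 0.00836 and 0.286 with 59, 136 and 54 animals, a 22.4-fold span on chromosome 11. Prdm16 on chromosome 4 had means of -0.926, -0.0163 and 0.220 with 71, 102 and 76 animals and a 14.0-fold span, its 2 upper components overlapping, and Ccnb1ip1 on chromosome 14, a gene of meiotic recombination, spanned 15.9-fold with 64, 133 and 52 animals. Skap2 on chromosome 6 had only 2 levels, with 168 animals low and 81 high and a span of 11.1-fold. Whether these counts match the shares that a dominant locus gives was not tested.

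Of 10278 autosomal genes, 134 were called discrete (simulated normal sets, adjusted p = 0.000229 for each of the 20 with the largest gain in likelihood, p = 1e-05, the smallest these can give). In 80 of them the middle mean was at least 2 within-component SD from both outer means, and 80 spanned at least 2-fold. The chloride channel gene Best1 (chromosome 19) spanned 6.17-fold, Lrrc6 (chromosome 15) 7.14-fold, Ccr6 (chromosome 17) 7.27-fold, Mro (chromosome 18) 5.79-fold and Aqr, a splicing helicase (chromosome 2), 5.26-fold. Gbp2b (20.1-fold) and Ugt8a (8.75-fold) lie on chromosome 3. Prkaa2, a catalytic subunit of AMP kinase, spanned 4.60-fold, H2-Bl 4.39-fold, Sfrp1, a secreted inhibitor of Wnt signalling, 3.56-fold, Paip1 3.43-fold, Abhd1 2.88-fold, the actin regulator Cap1 2.63-fold and the Wnt receptor Lrp6 2.50-fold. Gh and Cga were called too, with 0 animals in the low component, 190 and 187 in the middle one and 59 and 62 in the high one, as members of the pituitary group. So were Prl (181 and 68 animals in the middle and high components) and Tshb (189 and 60), and the olfactory bulb gene Tbx21 (162 and 87), all with 0 animals in the low component, so these 5 calls have 2 levels. Called genes lay on all 19 autosomes. In 78 of the 134 (58.2%) the gene with the strongest correlation lay on the same chromosome, against a mean of 5.47% and a highest value of 13.4% for shuffled positions (p = 0.001, the smallest these can give), a test added after the calls were seen.

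Among known strain variants, Alad, an enzyme of haem synthesis, was called (means -0.176, -0.000904 and 0.122, adjusted p = 0.000229 against simulated normal sets). Gabra2 (adjusted p = 0.135), Nnt (0.306), Pde6b (0.991) and Tlr4 (0.991) were not, and H2-Ea was not placed on an autosome here. Of the 5 tested, 1 passed over all genes tested and 2, Alad and Gabra2, passed when adjusted over the list alone (simulated normal sets, 0.0372 for Gabra2), but Gabra2 had an excess kurtosis of 1.29. The number of called genes depended on the settings, for reasons that were not tested: it was 198 without animal 144, with 133 of the 134 shared, 417 without the 12 arrays of largest spread, with 127 shared, and 863 under quantile normalization, with 98 shared. It was 936 without the condition on kurtosis, which removes a condition by construction. In simulated genes with outer means 4 SD apart 1 of 50 was called, so most loci of that effect or less may have been missed, although 28 of the 134 called genes had fitted spans under 4 within-component SD.

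**Figure D4:**
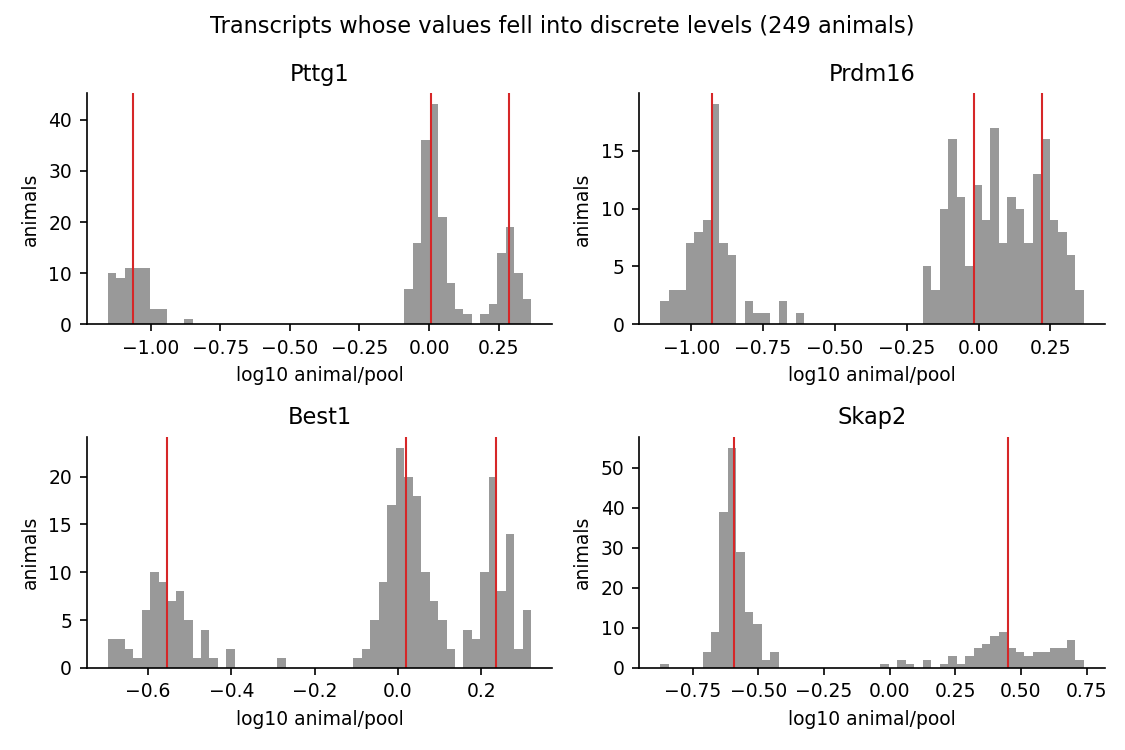
Histograms of the log10 ratio of discrete autosomal genes over the 249 animals, with the fitted means of the components as lines. Pttg1 has means of -1.06, 0.00836 and 0.286, while Skap2 has 2 levels.

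Genes that lie next to each other on a chromosome varied together more than genes at random. Among 10259 adjacent pairs on autosomes the mean r squared was 1.23 times that of random gene orders, and 786 pairs reached an absolute r of 0.5, of which 635 were positive and 151 negative. The pair BC002059 and Zfp97 on chromosome 17 had r = 0.861 and rho = 0.840 (permutation p = 1e-05 for each, 0.847 without 2 animals), but as the pair was picked for its large r among all adjacent pairs, this p is no test of it. The other 9 of the 10 named pairs held a clustered gene, so r is given within clusters of at least 6 animals. It was 0.833 in 186 animals and 0.462 in 63 for Gak and Dgkq on chromosome 5, 0.873 in 239 and 0.932 in 10 for Gm4767 and BC024063 on chromosome 10, and 0.809 in 240 and 0.259 in 9 for Smpd1, the acid sphingomyelinase gene, and Apbb1 on chromosome 7. For Pnpt1 and Mtif2 on chromosome 11 it was 0.716 in 192 and 0.568 in 57. With 1 cluster large enough, it was 0.832 for Pigf and Cript, 0.835 for H2az1 and Lamtor3, 0.796 for Gcc2 and Ranbp2, 0.577 for Ube2b and Ppp2ca, and 0.697 for the complement proteases C1ra and C1s1.

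The ratio to random orders was 1.13 at 2 to 5 places, 1.07 at 6 to 20, 1.03 at 21 to 50 and 1.02 at 51 to 100 (random gene orders, one-sided adjusted p = 0.0012 for each and for adjacent genes). It was 1.01 beyond 100 and up to 200 places (adjusted p = 0.0559), which did not pass, and passed without animal 144 (adjusted p = 0.02). With only the probes measured on every array, the ratio at 51 to 100 places did not pass (1.01, adjusted p = 0.127).

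**Figure D5:**
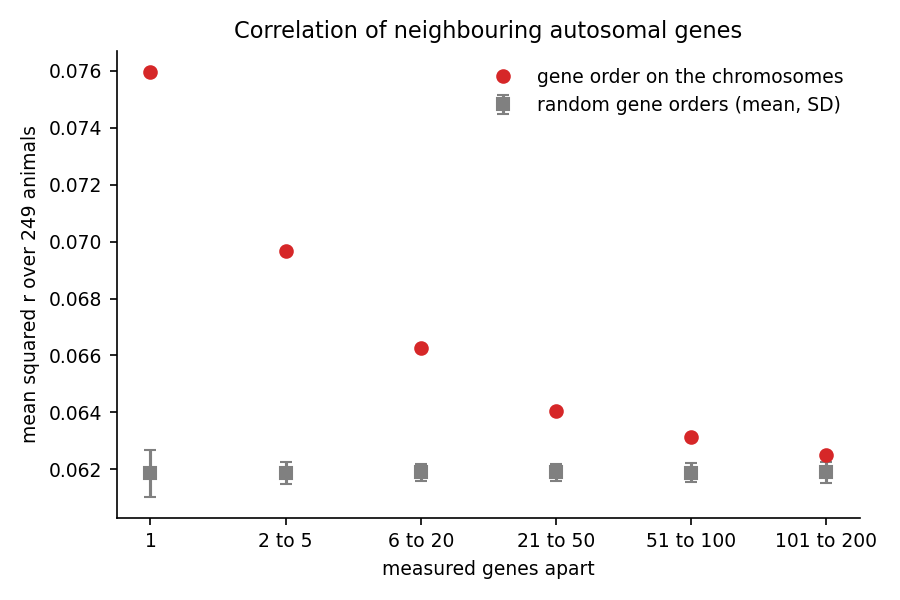
Mean r squared of autosomal gene pairs by the number of places between the genes, with the mean and SD of random gene orders. The ratio of the means to those of random orders falls from 1.23 for adjacent genes to 1.01 beyond 100 and up to 200 places.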

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

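Leaving out animal 144, alone or with animal 208, fitting lower and higher animal numbers apart and correlating lists within blocks of animal numbers were chosen after the results were seen, and the other alternatives were planned. No paired analysis was possible because the animals form 1 group and their numbers pair no groups. Correction of background, a filter on dim probes and the slide as a block were not run, since the values hold no intensities or slides, so what signal over background limits is unknown. The coherent lists numbered 24 to 31 under all alternatives tried, against 30. Coherence of single lists kept its side of the threshold in 436 of 519 comparisons, lost the call in 44, gained it in 27 and turned, losing the call with a negative mean r, in 12. The direction of lists that kept their side was not counted. The turned ones were neurons and GABAergic interneurons, with mean r of -0.00671 and -0.00197 under quantile normalization, -0.0885 and -0.0248 without the 12 arrays of largest spread, -0.101 and -0.0376 without animal 144, -0.101 and -0.0374 without animals 144 and 208, -0.104 and -0.0206 in animals with higher numbers, and -0.0817 and -0.0044 by Spearman correlation. Animal 144 alone is enough to turn both. Of 200 spans of named discrete genes 197 kept their call and 3 lost it, of 52 correlations of lists 45 kept it and 7 lost it, and of 224 SDs of named genes 174 stayed within the 95% interval of their bootstrap error and 50 moved beyond it. Genes with an SD of at least 0.2 numbered 80 to 154, against 119, except by the median absolute deviation (35), which shared 11 of the 25 genes of largest SD. Pairs of lists that passed numbered 5, and 4 to 6 under the alternatives not named next, against 76 under quantile normalization, 62 without the 12 arrays, 28 without animal 144, 57 with principal component 1 removed and 19 in animals with higher numbers, where more scores formed no clusters, so that 171, 153, 78, 120 and 91 pairs were tested in place of 15. Neighbours kept their call up to 50 places under each alternative tried. At 51 to 100 places the ratio was 1.0065 with only probes measured on every array, which did not pass. Beyond 100 and up to 200 places it passed at 1.0275 under quantile normalization, 1.0183 without the 12 arrays, 1.0136 without animal 144, 1.0125 with principal component 1 removed, 1.0146 in animals with higher numbers and 1.0177 by Spearman correlation. The cause was not tested for neighbours. Discrete genes numbered 134, against 863 under quantile normalization (98 shared), 417 without the 12 arrays (127 shared), 514 with values limited to 3 median absolute deviations (134 shared) and 936 without the condition on kurtosis (134 shared). The last removes a condition by construction, and for the others the cause was not tested. The other alternatives gave 119 to 198 called genes.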

Other observations

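All tests in this part were chosen after the results were seen, except that the outcome expected of the first locus scan and of the other probes of the Pttg1 partners was written down before those tests were run.

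A single animal stood out for the interferon response. In animal 208 Ifit1 was 10.8-fold above the pool, Ifit3 9.08-fold, the interferon regulatory factor Irf7 8.78-fold and Usp18 6.98-fold, and its list score was 7.78, with scores of 7.02 for MHC class I, 4.32 for acute phase and 4.13 for immunoglobulin and lymphocytes. Animal 348 followed at an interferon score of 3.23, with Oasl2 at 3.62-fold and Ifit1 at 2.82-fold. Isg15 was at 1.15-fold and 1.02-fold in these animals. The skeletal muscle scores were highest in animals 180 (4.67), 330 (4.39) and 2 (3.88).

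Genes of neutrophils and bone marrow, a list added after Ngp and S100a9 were seen among the 25 genes of largest SD, had a mean r of 0.502 over 10 members (random lists, adjusted p = 0.0003) and 0.504 without animal 144. The scores were highest in animals 183 (3.65), 178 (3.56) and 30 (3.40), and animal 178 also had the second highest SD over probes, 0.258. The added lists of liver (mean r -0.0374), testis (0.0463), kidney (0.0488) and intestine (-0.00165) were not coherent, and the lung list went from 0.565 to 0.145 without animal 144 and passed both times. In the 80 discrete genes with 3 separate means the middle mean lay near the midpoint of the outer means on the linear scale: its median offset was 0.00966 of the distance from the midpoint to an outer mean (quartiles -0.0384 and 0.0551), against 0.227 on the log scale, and 69 of the 80 were nearer the linear midpoint. Genes whose middle mean lay near an outer one, such as Skap2, were left out by the choice of the 80. The offsets therefore describe these 80 only.

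Lung transcripts were high on the array of animal 144, and most of them were low against the pool on the other 248. Weak signal or dye bias of genes that brain lacks is argued against, since the lowest of the medians of the liver, testis, kidney and intestine lists on those arrays was 0.00281. Lung tissue in the sample of animal 144 is a candidate explanation, with a lung list median of 0.776 on its array against at most 0.0492 for these 4 tissues. The added list of neutrophils and bone marrow was also raised on that array, with a median of 0.344. Lung RNA in the pool is a candidate as well, since 88.7% of the genes with a mean under -0.3 (47 of 53) were over 0.3 on that array, against 17.7% of all genes. Whether an equal portion from this animal could make up all lung RNA in the pool cannot be told apart from other sources. With the mean of the other 248 arrays taken as background, its lung transcripts were 5.99-fold above the pool (median of the 10 lung genes with a mean under -0.3 on those arrays, 2.04-fold to 30.6-fold). This is far below the number of portions, but true background and saturation of bright spots are unknown. The design gives no group that would allow a biological explanation to be tested.

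Transcripts of pituitary, cerebellum and olfactory bulb differed between brains, many of them with a low and a high part of the animals. For the pituitary, principal component 1 of the arrays (14.5% of variance) is argued against as the cause, since the mean r was 0.719 after its removal. Component 2 (11.7%) was not removed, so other common components of the arrays stay open. Differing amounts of pituitary taken with the brain may explain the pituitary pattern. Prl, Gh, Cga and Tshb placed 88.4% of animals (220, with 48 high and 172 low) on the same side, against at most 39.0% in 1000 shuffles. This count restates that they vary together, Cga and Tshb share a cell type, and a change in the whole gland stays open. A change along the animal numbers may contribute for the olfactory bulb, whose score fell with the number (r = -0.287, rho = -0.253, permutation p = 1e-05, the smallest these can give, and 7e-05, adjusted p = 0.000303 for rho, r = -0.286 without 2 animals), though 7 of the 13 lists set against the number passed, so this is not particular to that region. One inherited locus cannot be told apart from these: the highest window of 51 neighbouring genes reached p = 0.00799 by means, which meets what was written before for a locus, but that window held Epcam, itself varying with the pituitary genes, and after this was seen the scan was repeated without Epcam (p = 0.0879) and by medians (p = 0.269), and the first scan was no longer counted for a locus. The scans found the windows of Pttg1 (p = 0.001 by means, 0.0210 by medians) and Prdm16 (0.001, the smallest these can give, for both), but not that of Skap2 (0.387 and 0.142), a control added to the medians afterwards, and while the labels give no sex per animal, a difference that follows the Y-linked genes is argued against as the whole cause for the pituitary, whose mean r was 0.724 after regression on them.

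The discrete gene Pttg1 had 28 partners with an absolute r over 0.5, 5 on chromosome 11 and 23 on 11 other chromosomes, among them Gli3, H4c1, Myl10 and Ferd3l, and none of the 23 was itself called discrete. Principal component 1 of the arrays is argued against as the cause, since 100% of the 23 kept an absolute r over 0.5 after its removal. Further components were not removed, so other common components stay open. For the 4 partners with more than 1 probe, Sema6d, Hmgb2, Jpt2 and Tada3, to which this test was narrowed afterwards, an effect of the locus on the transcripts themselves is argued against for the 4 together and not for each, since in 100% of them another probe of the same gene had an r under 0.2, against 36 of 110 genes (32.7%) on the chromosome of a discrete gene they vary with (exact binomial, one-sided p = 0.0115, or 0.0281 at the share for their number of probes), a comparison added afterwards. The groups overlap, since Jpt2 is also among the 110 and the 36, through the discrete gene Gfer on its own chromosome (absolute r 0.625). Probes that also bind the Pttg1 transcript are a candidate explanation, as all 23 correlations were positive, but an effect of the locus may also give positive signs, and this count was first taken to decide nothing and read as favourable only after it was seen. For the other 19 partners, each with 1 probe, an effect of the locus stays open, as probe sequences are not analysed here, and within the low, middle and high components of Pttg1 the median r of the 23 was -0.0998 (-0.546 to 0.359), 0.120 (-0.307 to 0.290) and 0.00387 (-0.260 to 0.297).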
